A study of Mus musculus with 8 samples.

How the data were processed

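Gene expression was measured in Ly-6C-high monocytes, a subset of circulating phagocytes marked by a high surface level of the antigen Ly-6C, sorted from the blood and from the spleen of healthy, untreated C57BL/6 mice, an inbred laboratory strain. Per the labels, 4 female mice aged 8 to 12 weeks were used. The sort kept cells that were high for CD11b and Ly-6C, and low for a set of T cell, B cell, NK cell and granulocyte antigens (CD90, B220, CD49b, NK1.1 and Ly-6G) and for F4/80, I-Ab and CD11c. Each sample held 1000 sorted cells whose RNA had an integrity number of 8 or more, and 5 ng of RNA was amplified and labelled with the dye Cy3. The 8 samples form 2 groups, 4 from blood and 4 from spleen, numbered 1 to 4 within each tissue. The design text states that blood and splenic cells of each mouse were taken, but no label says that a number stands for a mouse, so the samples were compared as unpaired groups.

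The deposited data are of 2 kinds. Of these, the first is a scanner file per sample with spot intensity values, which per the file headers came from Agilent Feature Extraction 9.5.1.1, with 1 colour, local background subtraction and no normalization between arrays. Each array held 45018 spots, and 41174 different probes remained once control spots were left out. The other is a value table covering all 8 samples on a log2 scale made by the authors, for which the submitters' processing notes name limma, with its version not given in the sources used here. Where a scanner file and a table column came from the same array, the table ranked its probes as the scanner's median spot signal did, and all 8 columns had the same median, 7.31. The deposited log2 values are therefore read as quantile-normalized median signals without background subtraction, which narrows the differences of dim probes. Neither the table nor the files state this. Between 583 and 1426 cells per column were empty.

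The scanner files of blood 1, blood 2 and blood 3 did not hold the arrays of the table's columns for the same samples. Their rank correlations with their own column were 0.842, 0.852 and 0.872, while those of blood 4 and all 4 spleen samples rounded to 1. Empty cells of the table fell on spots whose local background the scanner software had marked as an outlier in 98.1% to 99.8% of cases in those 5 samples, and in 9.10%, 28.9% and 16.7% of cases in the other 3. Before the data were examined, the plan was to analyse log2 of the scanner's background-subtracted signal minus each array's 75th percentile. That plan was changed after this mismatch was seen: the authors' value table is the source of every value unless another is named, and the planned setting is given as an alternative. The change rests on the ranks and not on any comparison between tissues, but it was made after the data were examined. Which of the 2 deposits holds the intended blood samples is not stated in the sources used here.

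Probes were named through the accession in the scanner files, matched without its version to a RefSeq table of the mouse, which named 22951 probes (55.7%). The other 18223 kept the name in the scanner file. Probe positions are those in the scanner files, on the mouse build mm7. No exon or untranslated region annotation was used here.

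A level of 6.8 in the table was taken as the background level. In each of the 5 matching arrays, at least 95% of the probes in every step of 0.1 from this level up were well above background by the scanner software's own test. Probes were kept when they reached it on at least 4 of the 8 arrays and had at least 3 values per tissue, which left 25471 probes. A gene with several probes was represented by the brightest, which gave 18266 tested genes. The 5 matching arrays had 26539 to 29572 probes well above background, and the number of arrays limits the precision. Where a probe lay below the background level on every array of a tissue, the difference is a bound. It is given as "at least", from the mean of the brighter tissue minus the background level.

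Spleen was compared with blood by a linear model with moderated variance (lmFit and eBayes of limma 3.58.1 in R 4.3.3, with data.table version 1.17.8), and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. All differences are spleen minus blood on the log2 scale. Confidence intervals are 95% intervals from this model. A set of 32 gene lists, fixed before the data were examined, was tested with limma's camera at a preset correlation between genes of 0.01, for lists with 5 or more tested members, and adjusted over the lists. Camera with an estimated correlation and limma's fry were alternatives. Missing values were replaced by the tissue mean for these set tests only. Similarity was the mean Pearson correlation over genes of pairs of arrays within a tissue minus that between tissues, with an exact one-sided permutation test over the 35 splits of 8 arrays into 2 groups of 4.

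The rule for named genes was also fixed in advance. It takes up to 10 genes per direction that pass the threshold and do not overlap between tissues, filled to 10 by the smallest p where fewer pass, every measured antigen of the sort, the 3 members with the smallest p of each list that shifted, and a few genes set in advance, of which Ccr2, Csf1r, Cx3cr1, Agtr1a and Cxcr4 are reported here. Predicted genes and clones were left out of the first part. Other genes are said to have been chosen after their values were seen.

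The tests were checked on simulated data made from the means and spreads of the 18266 genes, with 200 changed genes in each of 5 draws. The model recovered 10.3% of genes changed 2-fold, 81.6% of those changed 4-fold and 96.8% of those changed 8-fold, with a false share of 5%. A list shift of 0.5 was found in 5 of 5 draws. The draws held independent noise per gene, without missing values or effects shared by genes, so these shares may not hold in the real data. The alternatives were the filter on dim probes, the way probes of a gene are combined, an intensity trend with robust variance, array weights, the replicate number as a fixed or random block, each array left out in turn, the overlap of lists and a rank correlation. Others used the scanner files, with 75th percentile, quantile or median scaling, with normexp background correction at an offset of 50, or with the slide as a block. Alternatives with normexp on the table, and with only the 5 matching arrays of either source, were added after the data were examined. The slides of the arrays behind the table's blood 1, 2 and 3 columns are unknown, so no slide block could be fitted to the table.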

Results

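The series compared Ly-6C-high monocytes held in the spleen with those circulating in the blood, as its title states, to ask how alike the 2 populations are. RNA of 4 blood and 4 spleen samples was hybridized to 1-colour arrays, and the comparison rests on 18266 genes that were above the background level on at least 4 of the 8 arrays. The values are those of the authors' value table, because 3 of the deposited blood scanner files hold other arrays than that table. P-values measure the spread between these samples, which came from 4 mice with both tissues taken from each. The main test takes the 8 samples as unpaired, so it may ignore a pairing by mouse. With the replicate number as a random block, at a correlation of 0.21, 13 genes passed the adjusted threshold.

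The largest differences were in genes of neutrophil granules and of cell division, which were brighter in all 4 spleen samples than in any blood sample. Ltf, which encodes the iron-binding granule protein lactotransferrin, was 8.34 ± 1.39 (SD, n = 4) in blood and 13.88 ± 0.74 (SD, n = 4) in spleen, 5.54 ± 0.65 (SE) higher. Camp, the gene of the antimicrobial peptide cathelicidin, was 8.77 ± 1.64 in blood and 14.35 ± 0.59 in spleen, and S100a8, one chain of calprotectin, was 8.82 ± 1.59 and 14.40 ± 0.71. Blood 2 was below the background level for these 3 genes, and without it the differences were 4.89 for Ltf, 4.76 for Camp and 4.897 for S100a8. Wfdc21 was 5.04 ± 0.62 (SE) higher in spleen, and Lcn2, which encodes the siderophore-binding lipocalin 2, was 3.97 ± 0.45 higher. Top2a, the topoisomerase that untangles DNA in dividing cells, was 3.09 ± 0.39 higher. Lcn2 and Top2a lay below the background level on 3 of 4 blood arrays, so the size of their differences is uncertain. Lower in all 4 spleen samples was Ctla2b, at 9.53 ± 0.42 in blood and 7.29 ± 0.03 in spleen, a difference of -2.24 ± 0.24 (SE). These 7 genes shared the smallest adjusted p of 0.0536, so none passed the threshold in that test. All 7 passed with a random replicate block, with an intensity trend, with array weights and with the mean over probes, while Camp and Ltf passed without blood 2 (adjusted p = 0.00756 and 0.0265), Ctla2b without blood 1 (0.0269), Top2a without spleen 1 (0.0432) and Lcn2 without spleen 2 (0.0146).

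In limma's test 0 of 18266 genes passed the adjusted threshold. At an unadjusted p under 0.05 there were 992 genes, 564 higher and 428 lower in spleen, of which 29 differed at least 4-fold. Variants of the same test gave 0 to 13 genes: 13 with the replicate number as a random block, 9 with array weights, 8 with an intensity trend and robust variance, 7 with the mean over a gene's probes, 2 with normexp, 1 each with the number as a fixed block and with probes above background on all 8 arrays, and 0 without a filter on dim probes, with each probe on its own and with the 5 matching columns. The count was 3 without blood 1, 2 without blood 2, 3 without spleen 1, 1 without spleen 2, and 0 without blood 3, blood 4, spleen 3 or spleen 4. The scanner files at the 75th percentile, the setting planned first, gave 4 genes, 1 higher (Lcn2) and 3 lower. In the simulated data the same test recovered 81.6% of genes changed 4-fold and 10.3% of those changed 2-fold. Those data held independent noise per gene and 200 changed genes, so the shares do not measure the power in the real data. There, 96.8% of genes changed 8-fold were recovered, while in the real data Ltf, 46.5-fold higher in spleen, did not pass. Intervals lay within 2-fold for 65.9% of the unchanged simulated genes and for 55.1% of the real genes.

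Among the other genes named as highest, none passed in that test, though Cdca8, Uhrf1, Rad18 and Pbk did with a random replicate block, Cdca8 also with array weights and Pbk with an intensity trend. Cdca8, a member of the chromosomal passenger complex of mitosis, was 2.98 ± 0.40 (SE) higher in spleen, and Uhrf1, which maintains DNA methylation during replication, was 2.63 ± 0.38 higher. Like Rad18, it lay below the background level on 3 of 4 blood arrays, which leaves the size of both differences uncertain. Rad18, a ubiquitin ligase of DNA damage tolerance, was 1.54 ± 0.22 higher, and 0.58 to 0.90 higher without blood 4, spleen 1, spleen 2 or spleen 4, when its other probe represents it. Pbk, a mitotic kinase, lay below the background level on all 4 blood arrays and was at least 1.69-fold higher in spleen. Their adjusted p-values were 0.0676 for Cdca8 and 0.0849 for Uhrf1, Rad18 and Pbk. Among the genes named as lowest, Ctla2a, a close relative of Ctla2b whose transcripts may not be told apart by every probe, differed by -2.59 ± 0.35 (SE, adjusted p = 0.0676). Ctla2a passed with a random replicate block, with array weights and without blood 1, and Etfbkmt with a random replicate block. Gng11, a G protein subunit, differed by -1.81, Etfbkmt by -1.49, Ezh1, a histone methyltransferase, by -1.43, Yae1d1 by -1.42, Irgq by -1.40, Lrrc8c, a subunit of volume-regulated anion channels, by -1.31 and Sh3bp5l by -1.19, with adjusted p-values from 0.0984 for Etfbkmt to 0.422 for Irgq. Mpp7 lay below the background level on all 4 spleen arrays and was at least 2.17-fold lower there, but its sign turned in every setting that used the scanner files or the 5 matching arrays, and in the table when any 1 of the 4 blood arrays was left out, as another of its probes then represents it.

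The probes lie, on mm7, on chromosome 9 from 110738071 to 110738130 for Ltf and from 109544107 to 109544166 for Camp. That of S100a8 lies on chromosome 3 from 90800058 to 90800117 and that of Wfdc21 on chromosome 11 from 83822431 to 83822490. For Lcn2 the span is 32392828 to 32393072 on chromosome 2, and for Top2a it is 99104969 to 99105783 on chromosome 11. Ctla2b and Ctla2a lie near each other on chromosome 13, from 60003833 to 60003892 and from 60042051 to 60042110.

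**Figure D1:**
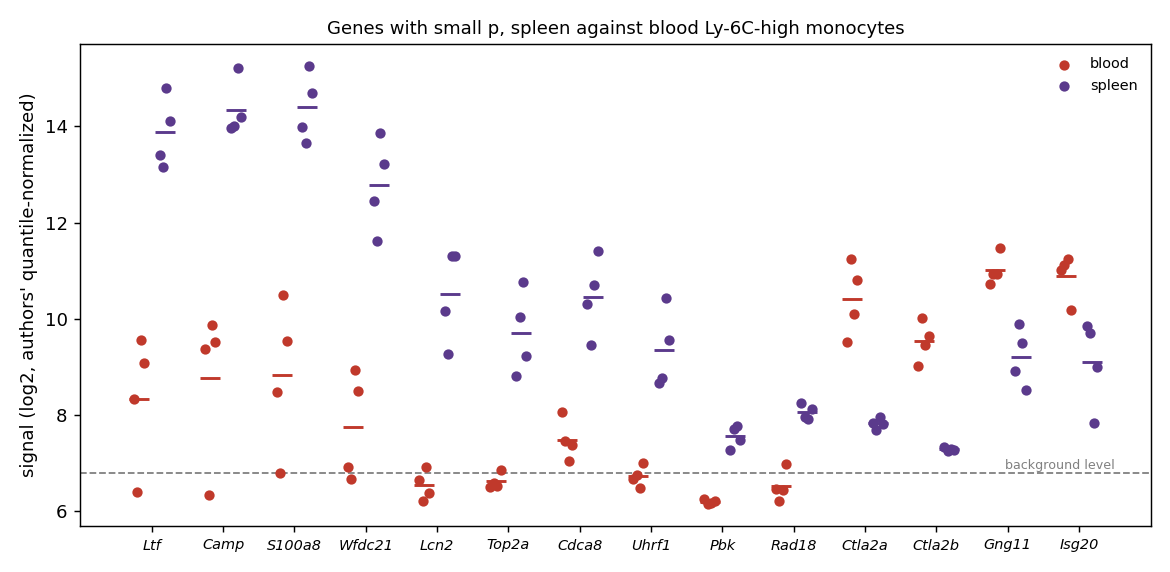
Log2 signal of named genes in each sample, in the authors' normalized values, with blood and spleen samples as points and the group means as lines. For Ltf the 4 spleen samples lie between 13.16 and 14.80, above all 4 blood samples, which lie between 6.39 and 9.55.

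For 10065 genes (55.1%) the 95% confidence interval of the difference lay within 2-fold in either direction. Without a filter on dim probes it was 19301 of 28402 genes. It was 2800 of 20943 genes with the scanner setting planned first and 2509 of 20943 with median scaling of those files. Both of these include the 3 mismatched blood files, so they do not show the effect of processing alone. The 4 spleen values lay entirely above the 4 blood values for 344 genes and entirely below for 258, together 3.30% of the genes, where chance gives 2.86%. The mean correlation of pairs of arrays was 0.913 within blood, 0.906 within spleen and 0.907 between the tissues. Within-tissue pairs were thus more alike by 0.00273. The exact one-sided permutation test did not separate this from chance (p = 0.171, where the smallest possible with 35 splits is 0.0286). That test takes the arrays as exchangeable, but both tissues came from each mouse, so it may ignore a pairing. Same-numbered samples count as pairs between tissues. Their deviations correlated by 0.091 to 0.14, against at most 0.033 for other numbers. Such likeness would narrow the difference, so the test cannot decide whether the tissues are alike. With 1 array left out the difference was between 0.000552 (without blood 1, exact permutation p = 0.486) and 0.00535 (without spleen 2, 0.0571). The scanner setting planned first, which includes the 3 mismatched blood files, gave 0.0182 (exact permutation p = 0.114).

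None of the antigens used in the sort passed over all genes. Itgam, which encodes CD11b, was 12.11 in both (SD 0.11 in blood and 0.18 in spleen, n = 4), Ptprc, the gene of CD45 including B220, was 14.40 in both, and Adgre1, the gene of F4/80, was 13.10 in both. Ly6c1, the gene of Ly-6C, differed by -0.33 ± 0.27 (SE), and H2-Ab1, a chain of I-A, by 0.47 ± 0.42 (95% interval -0.46 to 1.41). Itgax, the gene of CD11c, was 7.39 ± 0.81 (SD, n = 4) in blood and 9.20 ± 0.76 in spleen, higher in all 4 spleen samples, with an adjusted p of 0.57. Thy1, Itga2 and Klrb1c, which encode CD90, CD49b and NK1.1, were below the background level on at least 7 of 8 arrays, and Ly6g and Ly6c2 are not named on the array. A second probe that the files name Ly6c had values on 4 arrays, 15.15 and 15.25 in blood 3 and 4 and 13.92 and 14.63 in spleen 3 and 4, and was not tested. Over the 6 measured antigens, 5 were higher and 1 lower in spleen; 0 passed over all genes and 1, Itgax, passed when adjusted over the list alone. The list did not shift (adjusted p = 0.376). In the 6 settings with all scanner files Ly6c1, H2-Ab1 and Itgax had the opposite sign, but not with the 5 matching files alone.

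Genes set in advance for their role in monocytes also showed no difference that passed. Ccr2, the receptor that guides monocytes out of the marrow, differed by -0.41 ± 0.24 (SE), with 4 blood and 3 spleen values. Csf1r, the receptor for the monocyte growth factor, differed by 0.15 ± 0.29, and Cx3cr1 by -0.07 ± 0.30. Agtr1a, an angiotensin II receptor, was 7.11 ± 0.10 (SD, n = 4) in blood and 7.14 ± 0.47 in spleen, close to the background level. Cxcr4, which retains cells in marrow, was 0.80 ± 0.65 (SE) higher in spleen, and 0.11 higher without blood 1. The adjusted p was 1 for all 5 of these genes. In the 6 settings with all scanner files the signs of Ccr2, Cx3cr1 and Agtr1a turned; with the 5 matching files only that of Cx3cr1 did.

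Proliferation genes rose as a group in spleen. Of the 39 measured, 35 were higher and 4 lower, with a median difference of 0.85 (camera, adjusted p = 1.3e-19). None passed over all genes and 13, all higher, passed when adjusted over the list alone; Top2a, Cdca8 and Pbk had the smallest p. The median was 0.46 without spleen 3, and spleen 4 minus blood 4, which shared a slide, gave 0.705. The list kept its call with an estimated correlation (adjusted p = 0.047).

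Neutrophil and granule genes rose as a group in spleen by a similar amount. Of the 30 measured, 25 were higher and 5 lower, with a median of 0.80 (adjusted p = 3.72e-17); none passed over all genes and 13, all higher, passed when adjusted over the list alone, led by Lcn2, Ltf and Camp. The call held with an estimated correlation (adjusted p = 0.047), and spleen 4 minus blood 4 gave 0.939. Neutrophils express these genes abundantly, and the sort selected against the neutrophil antigen Ly-6G. The 6 settings with all scanner files, which include the 3 mismatched blood files, gave 1.32 to 1.97, and the 5 matching scanner files gave 0.77. Markers of other cells that the gate could hold were not called in the table: the B cell list had a median of 0.16 (15 of 21 higher, adjusted p = 0.258), the T cell list 0.045 (12 of 21 higher, 0.375) and the NK cell list 0.21 (9 of 10 higher, 0.135). With all scanner files B cell genes (-2.07 to -1.52) and NK cell genes (-2.16 to -1.30) were called lower in spleen in all 6 settings and T cell genes in 4. Spleen 4 had the highest B cell list median, 9.04 against 7.25 to 7.97 in the other 7 samples.

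NF-kB feedback and target genes also rose as a group in spleen, 19 of 22 higher and 3 lower, with a median of 0.45 (adjusted p = 7.36e-07, and 0.0344 with an estimated correlation). Of the 27 listed genes 15 also stand in another list, and without such genes the median was 0.283 (adjusted p = 0.0031). None passed over all genes and 3 passed when adjusted over the list alone. These were Bcl2a1b, an inhibitor of apoptosis, at 9.90 ± 0.27 (SD, n = 4) in blood and 11.39 ± 0.44 in spleen, Cd83, an activation marker, 0.98 ± 0.23 (SE) higher with 3 spleen values, and Traf1, a signal adaptor of TNF receptors, 1.11 ± 0.32 higher. All 3 were lower in spleen in the 6 settings with all scanner files, where the list stayed higher but lost its call in 4. With the 5 matching scanner files, which hold 1 blood array only, the genes and the list (0.826) were higher. Spleen 4 minus blood 4 gave 0.555 for the list.

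Platelet and megakaryocyte genes fell as a group in spleen. Of the 27 measured, 19 were lower and 8 higher, with a median of -0.41 (adjusted p = 0.00126, and 0.047 with an estimated correlation). None passed over all genes and 2, Gng11 and Myl9, passed when adjusted over the list alone, both lower. Myl9, a myosin light chain, was 9.34 ± 0.69 (SD, n = 4) in blood and 8.00 ± 0.28 in spleen. Pf4, the platelet chemokine, was 10.07 to 10.64 in 3 blood samples and 6.39 in blood 1, against 6.30 to 7.16 in spleen; without blood 1 its difference was -3.64 with an adjusted p of 0.0126. The list median was -0.27 without blood 1 and also -0.27 without spleen 2, and spleen 4 minus blood 4 gave -0.337. The call was lost in the 6 settings with all scanner files and with the 5 matching arrays of the table, with 1 blood array (adjusted p = 0.067).

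Interferon-stimulated genes fell as a group in spleen in the table, 39 of 44 lower and 5 higher, with a median of -0.33 (adjusted p = 1.44e-08), but rose in the 6 settings that include the 3 mismatched blood files, by 0.69 to 1.06. With an estimated correlation the call was lost (adjusted p = 0.225 with an estimated correlation). With the 5 matching scanner files alone, 1 of them from blood, the median was -0.353. None passed over all genes, and 0 when adjusted over the list alone. Isg20, an exonuclease, differed by -1.80 ± 0.45 (SE), Ifi35 by -1.09 ± 0.25 with 3 spleen values, and Ifit3, which binds viral RNA, by -1.03 ± 0.32. Without spleen 2 the median was -0.496, and spleen 4 minus blood 4 gave -0.592.

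Markers of Ly-6C-low monocytes, the patrolling subset, rose as a group in spleen in the table, but were lower there in the 6 settings that include the 3 mismatched blood files, 2 of which called it. With the 5 matching scanner files alone, 1 of them from blood, the median was 0.426. Of the 23 measured, 16 were higher and 7 lower, with a median of 0.25 (adjusted p = 0.00285). The medians of the list per sample overlapped, 10.25 to 10.91 in blood and 9.87 to 11.55 in spleen, with spleen 1 the lowest. The call was lost with an estimated correlation (adjusted p = 0.102 with an estimated correlation) and without spleen 4 (adjusted p = 0.0984). None passed over all genes and 3 passed when adjusted over the list alone: Pglyrp1, which binds bacterial peptidoglycan, 1.68 ± 0.36 (SE) higher, Treml4, a receptor of the TREM family, 1.23 ± 0.27 higher, and Itgax. Pglyrp1 also stands in the neutrophil list. Spleen 4 minus blood 4 gave 0.611. Markers of Ly-6C-high monocytes had 5 members higher and 13 lower, with a median of -0.16 (adjusted p = 0.258), and 0 passed in either adjustment; the list was higher, and called, in the 6 settings with all scanner files, and at -0.018 with the 5 matching files.

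**Figure D2:**
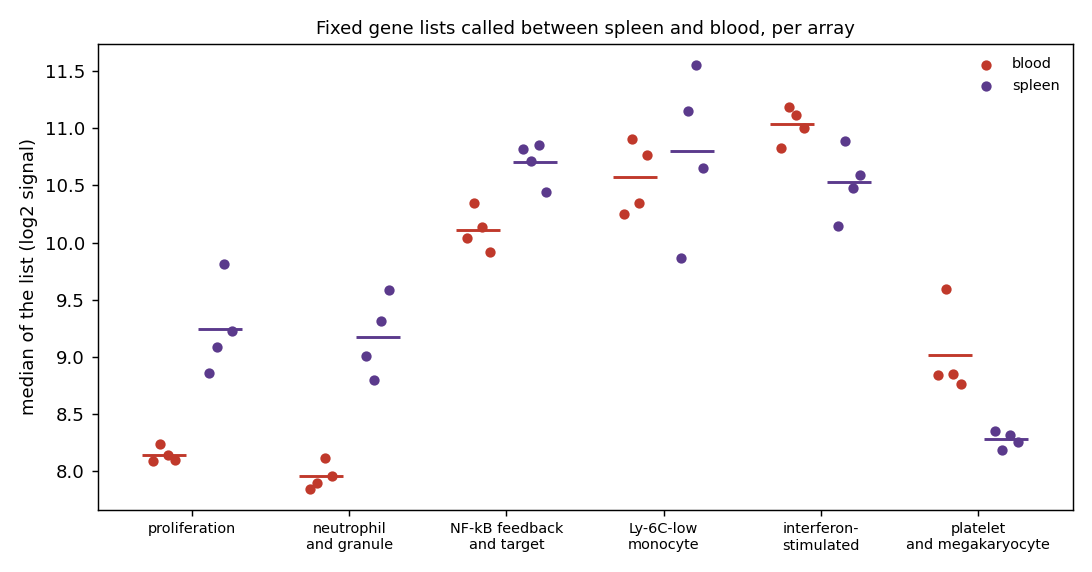
Median log2 signal in each sample of the gene lists that shifted (camera, adjusted p under 0.05). Blood and spleen samples are points and the group means are lines. The lists are ordered by their median difference, spleen minus blood, with proliferation genes (0.85) and neutrophil and granule genes (0.80) farthest to the left.

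Other lists did not shift. Each had 0 members past the threshold over all genes. Chemokine and lipid chemoattractant receptors had 14 members higher and 10 lower (adjusted p = 0.376), adhesion and integrin genes 15 and 15 (0.42), and MHC class II and costimulation genes 11 and 4 (0.258), with 1 member each, Cxcr2, Vcam1 and Cd83, passing when adjusted over the list alone. Dendritic cell genes had 19 higher and 10 lower (0.118), with Cd24a passing in the same way, and iron, heme and oxidative stress genes 20 and 14 (0.375), with Slc40a1. Apoptosis and survival genes had 15 higher and 20 lower (0.884), with Bcl2a1b passing alone. Of these, Cxcr2, Vcam1, Cd24a and Slc40a1 were named after their values were seen.

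In the following lists 0 members passed when adjusted over the list alone. Renin-angiotensin genes had 4 members higher and 6 lower (adjusted p = 0.376), heat shock and chaperone genes 10 and 9 (0.742), and erythroid genes 5 and 12 (0.529). B cell, T cell and NK cell genes were given above with the neutrophil list. Eosinophil, basophil and mast cell genes had 10 higher and 7 lower (0.376) and stromal and endothelial genes 13 and 13 (0.884). Glycolysis and hypoxia genes had 21 higher and 14 lower (0.527), lipid and cholesterol genes 21 and 16 (0.258), and protease and matrix remodelling genes 8 and 18 (0.163). Pattern recognition and Fc receptor genes had 25 higher and 15 lower (0.0502), and were called, higher, without blood 3 (0.00748), blood 4 (0.0453) or spleen 3 (0.0355), with normexp (0.0497) and in the 6 scanner settings. Ribosomal protein genes had 32 higher and 33 lower (0.915) and oxidative phosphorylation genes 50 and 28 (0.25), called, higher, in the 6 settings with all scanner files (5.56e-08 to 0.0149). In the settings with all scanner files, MHC class II, dendritic cell, eosinophil and protease genes were called in the opposite direction in 6 and apoptosis genes in 1, and iron and ribosomal genes in the same direction in 2 and glycolysis genes in 1. For adhesion and integrin, stromal and endothelial, and apoptosis and survival genes, the sign of the median differed from that of the mean.

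**Figure D3:**
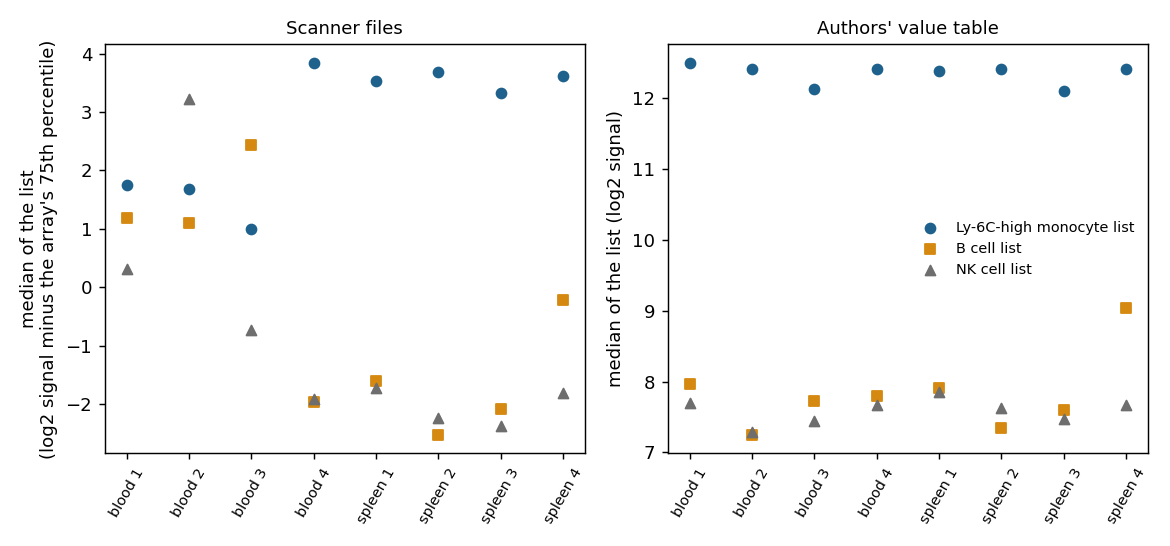
Comparison of each sample's scanner file with its column of the authors' value table. The files of blood 1, 2 and 3 reach rank correlations of 0.842, 0.852 and 0.872 with their own column, and the ranks of the other 5 match theirs.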

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

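All tests of explanations in this part were chosen only after the result was seen. A sample is listed when its gap to the nearest of the other 3 samples of its tissue is large for the range of the group. This held for 8 of 143 groups of 4 samples, where chance gives about 1 in 20.

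Camp was 6.34 in blood 2 and 9.37 to 9.87 in the other blood samples. Pf4 was 6.39 in blood 1 and 10.07 to 10.64 in the other 3. Cx3cr1, a chemokine receptor of patrolling monocytes, was 10.61 in spleen 4 and 9.87 to 9.93 in the other spleen samples. Irgq was 7.04 in spleen 3 and 6.55 to 6.62 in the others. Among list medians, Ly-6C-high monocyte markers were at 12.10 in spleen 3 against 12.39 to 12.41. Adhesion and integrin genes were at 10.06 in spleen 4 against 9.29 to 9.42, and red pulp and tissue macrophage genes at 9.30 in spleen 1 against 9.92 to 9.99. Platelet and megakaryocyte genes were at 9.60 in blood 2 against 8.76 to 8.85 in the other blood samples.

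The scanner files of blood 1, 2 and 3, which are not used for the comparison, held a signal for lymphocyte genes. Relative to each array's 75th percentile on the log2 scale, the median of the B cell and plasma cell genes was 1.194, 1.098 and 2.441 in these files and -2.53 to -0.23 in the 5 files that match the table. The median of the NK cell genes was 0.31, 3.23 and -0.73, against -2.37 to -1.73. The B cell gene Cd79b was at 5.17, 3.47 and 5.24, against 0.031 to 1.26. Ly6c1 was at 0.31, -0.22 and -0.73 and 3.34 to 4.35 in the 5 matching files, while Csf1r, at 4.36, 3.893 and 3.004, overlapped their range of 3.99 to 4.72 in 1 of the 3.

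The ranks argue against 2 explanations of these 3 files. If the same arrays had been processed in another way, each file would rank its probes as its own column does, but the highest rank correlation was 0.872. If files had been exchanged among the 8 samples, one would match another column, but the highest was 0.898. Arrays of RNA from cells other than Ly-6C-high monocytes may account for them: the Ly-6C-high list median lay at least 1.58 below that of every matching file, and the B cell list at least 1.32 above. Of the 34 genes on the B cell list 3 also stand in another list, the gate on B220 would remove B cells, and no further explanation was tested.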

How the results depend on the processing

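The settings with 5 matching arrays and with normexp on the table were chosen after the data were examined, as was the use of the table in place of the scanner files. Against 0 genes past the adjusted threshold, the scanner files of all 8 samples gave 4, 7, 5, 6, 4 and 1 with the 75th percentile, quantile, median, normexp with the 75th percentile, normexp with quantile and the slide block. The same counts were changed at least 2-fold. Other settings of the table gave 13 (random replicate block), 9 (array weights), 8 (trend and robust variance), 7 (mean of probes), 2 (normexp) and 1 (all 8 arrays above background), and 0 without a filter, with each probe on its own and with 5 arrays. Leaving out 1 array gave 0 to 3. Genes with an interval inside 2-fold numbered 10065, and 19301 without a filter, 1813 with 5 matching columns and 0 with 5 matching scanner files, where fewer samples widen the intervals. With all scanner files they numbered 2800, 3507, 2509, 7688, 9355 and 2878 with the 75th percentile, quantile, median, normexp with the 75th percentile, normexp with quantile and the slide block. Instead of 6 lists, 15, 14, 14, 18, 17 and 14 shifted in the 6 scanner settings, and 6 to 10 with 1 array left out, 10 without blood 3. Called lists kept direction and call in 22 of 22 settings without the 3 mismatched files (2 of them with 1 blood array) for proliferation (medians 0.46 to 1.02), neutrophil (0.55 to 0.89) and NF-kB genes (0.28 to 0.83). Without spleen 4, Ly-6C-low markers were at 0.215 (adjusted p = 0.0984). Platelet genes kept theirs in 21, with 5 columns at -0.38 (adjusted p = 0.067), interferon genes in 20 and Ly-6C-low markers in 19. With the scanner files, the platelet list had medians of -0.26 (adjusted p = 0.544), -0.24 (adjusted p = 0.494), -0.17 (adjusted p = 0.494), -0.22 (adjusted p = 0.577), -0.13 (adjusted p = 0.422) and -0.32 (adjusted p = 0.127). The NF-kB list had 0.22 (adjusted p = 0.0927), 0.35 (adjusted p = 0.063), 0.18 (adjusted p = 0.14) and 0.18 (adjusted p = 0.111) with quantile, median, normexp with quantile and the slide block. With an estimated correlation and with fry, the median of the interferon list stayed at -0.33 and that of the Ly-6C-low list at 0.25, and both calls were lost, with adjusted p of 0.225 and 0.188 for the first and 0.102 and 0.0578 for the second. Similarity had the same sign in all 19 alternatives, 0.00055 to 0.0182, with exact permutation p of 0.0571 to 0.486. These permutations did not allow for a pairing by number. Scanner settings moved the median over all genes to -0.105 with the 75th percentile and -0.175 with normexp and the 75th percentile. Of genes at an unadjusted p under 0.05, 56.9% were higher in the table, 43.8% with normexp and the 75th percentile and 45.1% with 5 columns. With the 5 matching scanner files, which hold 1 blood array, 8 lists shifted. The 6 settings with all scanner files hold other arrays for blood 1, 2 and 3 than the table. Their counts therefore do not show the effect of processing alone. The cause of the other changes was not tested.

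With the replicate number as a block, 1 gene passed (Wfdc21), also at least 2-fold, and no list lost its call. Inflammatory cytokines and chemokines were called (median 0.25, adjusted p = 0.0467), as they were with the mean over probes (0.00303), without a filter (0.0492), with normexp on the table (0.0494), with fry (0.0228) and without blood 2 (0.0104), blood 3 (0.00726) or spleen 4 (0.00465). They were not called with the number as a random block (0.0558), with an estimated correlation (0.136) or without genes of several lists (0.483). As a hint from the data and not from the design, the deviations of same-numbered samples correlated by 0.092, 0.14, 0.093 and 0.091. Each lay above every correlation with another number, which reached at most 0.033. The numbers were not taken as pairs, because no label ties them to mice and not all values were above 0.1. The main test may therefore ignore a pairing, and with the number as a random block 13 genes passed.

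In the lists of values that follow, the scanner files of all 8 samples were used with the 75th percentile, quantile, median, normexp with the 75th percentile, normexp with quantile and the slide block, in that order. The lists named next had a test of the opposite sign, with these medians. Ly-6C-high markers gave 1.32, 1.27, 1.41, 1.26, 1.22 and 1.16. Ly-6C-low monocyte markers had -0.21, -0.14, -0.12, -0.15, -0.15 and -0.17. MHC class II and costimulation genes reached -1.07, -0.99, -0.98, -0.76, -0.64 and -1.09. Interferon-stimulated genes came to 0.97, 0.93, 1.06, 0.82, 0.78 and 0.69. B cell and plasma cell genes gave -2.07, -2.07, -1.98, -1.66, -1.52 and -1.61. T cell genes had -0.39, -0.36, -0.30, -0.35, -0.17 and -0.27. NK cell genes reached -2.16, -2.13, -2.07, -1.57, -1.30 and -1.60. Dendritic cell genes came to -0.57, -0.46, -0.48, -0.47, -0.40 and -0.48. Eosinophil, basophil and mast cell genes gave -0.96, -0.86, -0.87, -0.70, -0.63 and -0.86. Protease and matrix remodelling genes had 0.63, 0.71, 0.72, 0.58, 0.52 and 0.55. Apoptosis and survival genes reached 0.061, 0.058, 0.15, 0.032, 0.068 and -0.075. The named genes below had the opposite sign, with these log2 differences. Agtr1a gave -0.49, -0.36, -0.40, -0.39, -0.18 and -0.034. Bcl2a1b had -0.35, -0.43, -0.26, -0.38, -0.49 and -0.12. Ccr2 reached 1.40, 1.31, 1.48, 1.44, 1.30 and 1.27. Cd83 came to -1.73, -1.75, -1.64, -1.72, -1.59 and -1.47. Cx3cr1 gave 0.74, 0.73, 0.83, 0.66, 0.64 and 0.75. H2-Ab1 had -1.26, -1.26, -1.17, -1.19, -1.23 and -1.46. Ifit3 reached 2.95, 2.88, 3.04, 2.61, 2.52 and 2.46. Isg20 came to 0.95, 0.97, 1.04, 0.73, 0.69 and 0.63. Itgax gave -1.21, -1.22, -1.12, -1.42, -1.33 and -1.20. Ly6c1 had 2.83, 2.82, 2.92, 2.76, 2.68 and 2.49. Mpp7 reached 1.39, 1.66, 1.48, 0.20, 0.026 and 1.48. Traf1 came to -1.02, -1.04, -0.94, -1.01, -1.02 and -1.13. With the 75th percentile and only the 5 matching scanner files, all of these lists and genes had the sign of the table again (for lists that of the test), except NK cell, protease and apoptosis genes, Cx3cr1 and Mpp7, and the medians of dendritic cell genes (-0.0995) and eosinophil genes (-0.021), whose tests turned back. That comparison has 1 blood array. MHC class II, B cell and eosinophil genes and Agtr1a also turned in some settings of the table, given in the next paragraph. For the rest the sign turned only where the 3 mismatched files were included. For these genes and lists and for the exceptions above, the cause was not tested.

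In a few settings only, the sign turned as follows; for lists the sign is that of the test, which can differ from that of the median. Immediate-early genes were at -0.049 with the scanner files and normexp with quantile. Chemoattractant receptors were at -0.48 with the scanner files and the 75th percentile, -0.46 with the scanner files and quantile and -0.39 with the scanner files and median. Also, chemoattractant receptors were at -0.41 with the scanner files and normexp with quantile, -0.42 with the scanner files and the slide block and 0.072 with the 5 matching columns of the table. Also, chemoattractant receptors were at 0.058 with the 5 matching scanner files. Adhesion and integrin genes were at -0.016 without genes of several lists. Renin-angiotensin genes were at 0.0077 with the scanner files and the slide block. Erythroid genes were at -0.011 without a filter on dim probes. B cell and plasma cell genes were at -0.063 with probes above background on all 8 arrays. NK cell genes were at -0.044 with the 5 matching scanner files. Progenitor genes were at -0.15 with the scanner files and the 75th percentile, -0.16 with the scanner files and quantile and -0.060 with the scanner files and median. Also, progenitor genes were at -0.28 with the scanner files and normexp with the 75th percentile and -0.17 with the scanner files and normexp with quantile. Stromal and endothelial genes were at -0.00093 without a filter on dim probes, 0.0022 with probes above background on all 8 arrays and -0.0039 with the mean over a gene's probes. Protease and matrix remodelling genes were at -0.069 with the 5 matching scanner files. Apoptosis and survival genes were at -0.025 with the 5 matching columns of the table and -0.00058 with the 5 matching scanner files. Ribosomal protein genes were at -0.056 with the scanner files and normexp with the 75th percentile, 0.0084 without a filter on dim probes and -0.010 with the 5 matching scanner files. Adgre1 was at -0.085 with the 5 matching columns of the table and -0.0027 with the 5 matching scanner files. Agtr1a was at -0.0018 with array weights. Cx3cr1 was at 0.026 with array weights, 0.072 with the 5 matching columns of the table and 0.058 with the 5 matching scanner files. Itgam was at -0.012 with array weights and -0.16 with the mean over a gene's probes. Mpp7 was at 0.40 with the 5 matching columns of the table and 1.32 with the 5 matching scanner files. Pglyrp1 was at -0.023 with the scanner files and the 75th percentile, -0.12 with the scanner files and quantile and -0.15 with the scanner files and normexp with quantile. Treml4 was at -0.084 with the scanner files and quantile and -0.059 with the scanner files and normexp with quantile. The cause was not tested, except that another probe represents Mpp7 where the first is not above background on enough arrays. Leaving out 1 array at a time turned the sign at least once for the following, with these lowest and highest values. Immediate-early genes -0.053 to 0.092, heat shock and chaperone genes -0.025 to 0.069 and adhesion and integrin genes -0.028 to 0.068. MHC class II and costimulation genes 0.042 to 0.41, B cell and plasma cell genes -0.046 to 0.24 and eosinophil, basophil and mast cell genes -0.037 to 0.12. Stromal and endothelial genes -0.084 to 0.038, apoptosis and survival genes -0.12 to 0.041 and ribosomal protein genes -0.080 to 0.057. Adgre1 -0.10 to 0.17, Agtr1a -0.13 to 0.21 and Csf1r -0.041 to 0.33. Cx3cr1 -0.25 to 0.18, Itgam -0.056 to 0.087 and Mpp7 -1.61 to 0.32. Ptprc -0.069 to 0.12.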

Other observations

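In this part the tests of mature neutrophil genes, of slides, and of the number of genes past the adjusted threshold were chosen only after the result was seen, as were the genes named in the next 2 paragraphs.

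Red pulp and tissue macrophage genes had 18 members higher and 11 lower in spleen, with a median of 0.14, and the list did not shift (camera, adjusted p = 0.0502; 0.134 with an estimated correlation). It lies at the threshold: 12 of 28 other settings called it, higher in spleen. These were fry (adjusted p = 0.0224), no filter on dim probes (0.00789), the mean over probes (0.0111), normexp (0.0494), the table without blood 3 (0.0297) or blood 4 (0.0354), and the 6 settings with all scanner files (0.009 to 0.0349). Its median was between 0.017 and 0.088, without a call, when blood 1, blood 2, spleen 1, spleen 2 or spleen 4 was left out, lowest without spleen 1 (adjusted p = 0.14). None passed over all genes, and 5 passed when adjusted over the list alone, all higher. Vcam1, an adhesion molecule of red pulp macrophages, was 6.63 ± 0.25 (SD, n = 4) in blood and 8.94 ± 0.78 in spleen. Slc40a1, the iron exporter ferroportin, was 6.78 ± 0.58 in blood and 8.95 ± 0.24 (n = 3) in spleen. Both lay below the background level on 3 of 4 blood arrays. Spic, the transcription factor of red pulp macrophages, was 1.48 higher, Cd81 1.56 higher and Actn1 1.37 higher. Other members went the other way or differed little: Axl differed by -0.54, Mrc1 by -0.36, Siglec1 by -0.36 and C1qb by 0.17.

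Progenitor genes had 9 members higher and 7 lower, with a median of 0.12 (adjusted p = 0.0829; median 0.30 and 0.0489 without blood 3, 0.51 and 0.0297 without blood 4; without a call, median 0.393 without blood 2 and -0.00617 without spleen 1), and 0 passed over all genes or over the list alone. Myb, a transcription factor of blood progenitors, was 0.78 higher and Mpo 0.87 higher in spleen, while Lmo2 differed by -0.50. Inflammatory cytokines and chemokines had 15 higher and 7 lower, with a median of 0.31 (adjusted p = 0.0502), with 0 past either adjustment. That list was called in 9 of 28 other settings, among them without blood 2 (0.0104), blood 3 (0.00726) or spleen 4 (0.00465), while its median was 0.20 without blood 1 (0.164) and 0.12 without spleen 2 (0.0671). Immediate-early genes, which respond within minutes to handling or stimulation, went both ways, 14 higher and 13 lower (median 0.0038, adjusted p = 0.624), with 0 past either adjustment. Fosb was 1.52 higher, Jun 0.94 higher and Dusp2 0.77 higher, while Gadd45b differed by -1.02, Atf3 by -0.91 and Egr1 by -0.81.

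Granule genes were higher in spleen. Spleen 4 and blood 4, on the same slide, differed by 3.86 over the 6 secondary granule genes without a missing value there. As this is a single pair and the slides of the table's blood 1, 2 and 3 are unknown, a difference between slides is not excluded. Mature neutrophils in the sort may contribute, but the median of mature neutrophil genes was 0.903 against 3.97 for 7 secondary granule genes, 1 of them, Ngp, with only 2 spleen values and no test. This does not decide, since a high blood level of genes such as Padi4 (10.1) could hide a small share. Precursors at the primary granule stage could also contribute, but primary granule genes had a median of 0.57. Of these, Elane was 9.16 in spleen 3 against 6.68 to 7.12 in the other spleen samples. Ctsg was 9.99 in spleen 2 against 7.65 to 8.015. Mature neutrophil genes ranged from 0.03 (Csf3r) to 2.59 (Cxcr2), and secondary granule genes from -0.08 (Mmp8) to 5.57 (Camp). These members were named after their values were seen. The explanations thus cannot be told apart from a difference of the monocytes themselves, which was not tested. Of the 38 listed genes, 10 also stand in another list, and Ly-6G, part of the gate, would remove mature neutrophils.

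Proliferation genes were higher in spleen too. Spleen 4 minus blood 4, on the same slide, gave a median difference of 0.705, again a single pair, so a difference between slides is not excluded here either. A higher share of dividing cells in the splenic sort may account for it, as may dividing precursors of granulocytes; neither was tested.

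The 8 arrays can be split into 2 groups of 4 in 35 ways. For 4 of the 6 called lists 1 split, the real one, reached as large an absolute median. That share, 0.0286, is the smallest possible and is not adjusted for having picked these lists by their call in the same split, so it does not by itself exclude chance for any of them. The real median and the highest of the other splits were 0.803 and 0.694 for the neutrophil and granule list, 0.85 and 0.677 for proliferation, 0.414 and 0.319 for platelets, and 0.446 and 0.345 for NF-kB. Chance cannot be excluded for the interferon list, where 4 splits reached 0.33 and the highest other gave 0.603, nor for the Ly-6C-low list, where 4 reached 0.247 and the highest other gave 0.264. The number of lists called, which picks no list, was 6, and 1 split, the real one, gave as many. As 3 other splits gave 5, the highest other value, and the share is unadjusted, this is weak ground on which to exclude chance. Those 3 splits, and the splits with the highest other medians, put 3 arrays of 1 tissue with 1 of the other. They thus keep part of the tissue contrast and do not show what chance alone gives. Splits with 2 arrays of each tissue per group called at most 3 lists. For genes past the adjusted threshold the real count is 0, so all 35 splits give as many whatever the data, and nothing was tested; the highest other gave 1.

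For genes at an unadjusted p under 0.05, 9 of the 35 splits gave as many as the real 992, so chance cannot be excluded. The highest other split gave 1933 and set numbers 1 and 4 of both tissues against numbers 2 and 3. Setting numbers 1 and 2 against 3 and 4 gave 1332, and 1 and 3 against 2 and 4 gave 841. An effect carried by the number was not tested, so such splits may hold more than chance. For genes with an interval inside 2-fold, 28 splits gave as few as the real 10065.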
